A study of Komagataella phaffii CBS 7435 with 16 samples.

How the data were processed

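RNA was sequenced from chemostat cultures of the wild-type methylotrophic yeast Komagataella phaffii CBS7435, which is used to produce recombinant proteins. The labels give 16 libraries in 4 groups of 4 biological replicates. They name the groups by oxygen (30% or 0%) and by the number of reactor volume changes at sampling: 30% oxygen at 5 volume changes, and 0% oxygen at 0.4, 4 and 5 volume changes. The treatment protocol describes the same 4 sampling points differently: 66 h at 21% inlet oxygen, then 5, 50 and 70 h after a switch to 8% inlet oxygen. Both descriptions are kept here, and the groups carry the names of the sample labels. Per the labels' protocols, cultures were glucose-limited at 25 °C and pH 5.5. Ribosomal RNA was depleted before directional libraries were prepared.

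Each deposited table lists 5564 features with a length, an effective length, an estimated count and a TPM value, per the file headers. The estimated count is the number of reads the authors' quantification assigned to a feature, without normalisation, and it need not be whole where reads are shared between features. The deposited TPM value is that estimated count divided by effective length and scaled to the same total in every library. The submitters' processing notes list cutadapt 1.18, Bowtie2 2.3.4.1, SAMtools 1.9, kallisto 0.44.0, R 4.2.0 and DESeq2 1.36.0, without saying what each was used for. The genome build, the annotation and the strand setting of the counting are not given in the sources used here.

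Identifiers end in t (5378 features) or r (186 features), and the tables do not explain these suffixes. Lengths of t features were multiples of 3 in 99.96% of cases, so they are called coding lengths here. The r features measured 66 to 6508 nt, and 176 of them were at most 120 nt long. Identifiers that contain "Mit" (16 t and 33 r features) were taken as the mitochondrial chromosome. The reference table used here, of assembly ASM2700v1, holds 5040 genes; 0 of them matched an identifier, and 0 carried a symbol. Features are therefore given by identifier, and genomic coordinates are not analysed here. Of the gene lists fixed before the data were examined, only the mitochondrial one could be matched. The lists for glycolysis, respiration, sterol, lipid and heme synthesis, protein folding, redox systems, methanol use and other pathways were not tested, and neither were single genes planned by symbol.

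Estimated counts were rounded to whole numbers. Totals ran from 23085262 to 40699763 estimated counts per library. Between 1.87% and 2.82% of features per library held a count more than 1e-06 away from a whole number. In edgeR 4.0.16 (R 4.3.3), features with low counts were removed with filterByExpr (112 removed, 5452 tested), TMM factors were computed, and a quasi-likelihood model with 1 mean per group was fitted to all 16 libraries. The 6 pairwise contrasts were tested with glmQLFTest, and a joint F test covered all 4 groups. P-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05, and changes of at least 2-fold were counted separately. Standard errors of log2 fold changes were derived from the F statistic. "Gene" is used below for a tested feature of either suffix.

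Identifiers were named by a rule fixed before the data were examined. Called features with a mean of at least 50 counts, and with all 4 values of one group above all 4 of the other, were ranked by fold change. At most 2 rising and 2 falling identifiers per comparison could be printed. They are printed for 0.4 volume changes against 30% oxygen and for 4 against 0.4 volume changes, and those 8 are followed in the other groups. The mitochondrial list was tested with camera (limma 3.58.1, preset correlation 0.01, two-sided). Shares of counts per library were compared with two-sided exact permutation tests, 18 in all, and 4 libraries against 4 allow no p below 0.0286. These tests of shares were chosen after the data were examined. Overlaps between comparisons with the same control libraries were set against 20 simulations of unchanged groups, against independent lists, and against splits of the controls.

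Scripts were tested on simulated data. For 0.4 volume changes against 30% oxygen, with 5452 genes simulated, 16% of 50 genes planted at 1.25-fold were recovered, 76% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 8 of 5252 unchanged genes were called. Here and in the simulations of unchanged groups, genes were drawn independently, so variation shared by many genes of a library is absent. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 19.2. Their log CPM values correlated at 0.962 to 0.995. The fitted biological coefficient of variation was 0.149.

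Alternatives set before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), no filter and a stricter one (50 counts in 4 libraries), fits of the 2 groups compared alone, a replicate block, robust dispersion, r and mitochondrial features left out, and each library left out in turn. For the mitochondrial list they were camera with an estimated correlation, fry, the block, TPM values and each library left out. Alternatives chosen after seeing the data left out replicate 4 at 5 and replicate 2 at 4 volume changes of 0% oxygen together, although replicate 3 at 5 volume changes lay farther from its group mean on the third principal component than replicate 2 at 4 did, and divided the mitochondrial list by suffix.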

Results

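Transcript abundance was measured by RNA-seq in 16 chemostat libraries of Komagataella phaffii, 4 per sampling point. One group was labelled 30% oxygen at 5 volume changes, and 3 groups were labelled 0% oxygen at 0.4, 4 and 5 volume changes. The protocol describes these points as 66 h at 21% inlet oxygen, and 5, 50 and 70 h at 8% inlet oxygen. The series concerns the effect of oxygen supply on organelle redox state and stress, and its design compares all conditions with each other. Total counts per library averaged 36841666 ± 3344413 at 30% oxygen, and 37705426 ± 2441128, 31615157 ± 1499727 and 34556716 ± 8081802 (SD, n = 4) at 0.4, 4 and 5 volume changes of 0% oxygen. The lowest library, replicate 2 at 5 volume changes, held 23085262.

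Of 5452 genes tested, 3432 (62.9%) differed among the 4 groups in the joint F test. The first principal component held 53.4% of the variance and separated all 4 libraries at 30% oxygen from the 12 at 0% oxygen. The second held 18.6% and separated 0.4 volume changes from 4 and 5 volume changes of 0% oxygen, which lay next to each other.

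**Figure D1:**
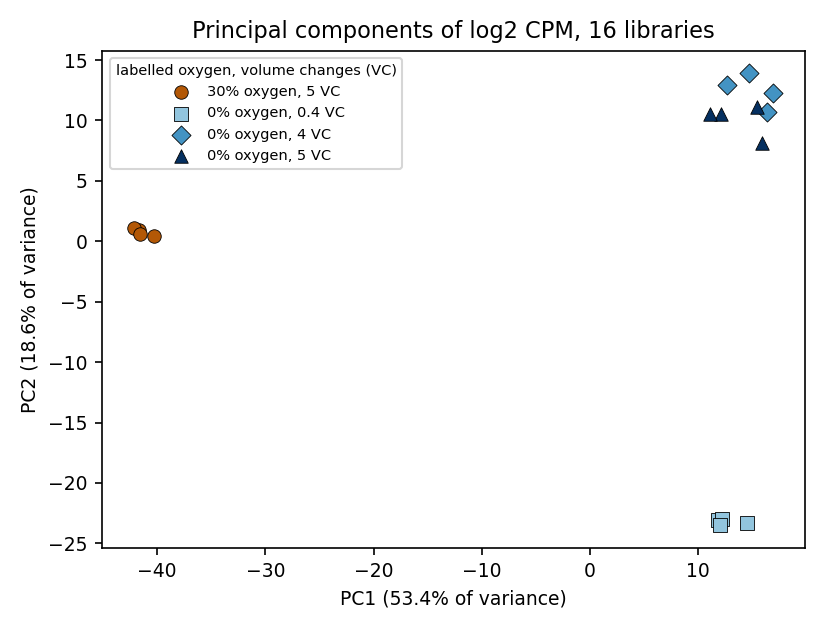
First and second principal components of log2 CPM for the 16 libraries, 1 point per library, with colour and shape giving the group. The libraries at 30% oxygen lie apart along the first component (53.4% of variance), and those at 0.4 volume changes of 0% oxygen along the second (18.6%).

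The first comparison asks what changed at the earliest sampling at 0% oxygen, 0.4 volume changes, relative to 30% oxygen. PP7435_Chr3-0810.t01, on chromosome 3 with a coding length of 2019 nt, rose from 2.1 ± 0.875 to 616 ± 30.2 CPM (SD, n = 4), a log2 fold change of 8.17 ± 0.25 (SE). PP7435_Chr2-0070.t01, on chromosome 2 (1413 nt), rose from 42.3 ± 8.22 to 1130 ± 72.6 CPM, a log2 fold change of 4.73 ± 0.16. PP7435_Chr1-3512.t01, a short feature of 123 nt on chromosome 1, fell from 1460 ± 144 to 2.87 ± 0.74 CPM, with a log2 fold change of -9.0 ± 0.21. PP7435_Chr3-0238.t01, on chromosome 3 (1098 nt), fell from 2160 ± 147 to 5.95 ± 0.517 CPM, with a log2 fold change of -8.50 ± 0.38. The adjusted p of these 4 features lay between 7.61e-16 and 2.34e-12 in edgeR's quasi-likelihood test.

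In that comparison 2606 genes were called, 1296 higher and 1310 lower at 0% oxygen. Most changes were small: the median absolute log2 fold change of called genes was 0.58. At least 2-fold, 245 genes rose and 358 fell; at least 4-fold, 59 rose and 114 fell. The 245 genes held 5.56% of normalised counts at 30% oxygen and 19.58% at 0.4 volume changes, and the 358 genes 12.75% and 2.90%, both sets having been chosen by the same test. Between 45.1% and 50.5% of the coding features of each numbered chromosome were called. On deposited TPM values 31.4% of called genes were higher, against 49.7% in the main test. The median log2 fold change of all genes was -0.127 on TPM values and 0.008 in the main test.

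The comparison of 4 volume changes of 0% oxygen with 30% oxygen asks what differed after longer exposure. The features named above kept their directions: PP7435_Chr3-0810.t01 stood at 710 ± 100 CPM and PP7435_Chr2-0070.t01 at 962 ± 174 CPM, while PP7435_Chr1-3512.t01 stood at 1.45 ± 0.356 and PP7435_Chr3-0238.t01 at 4.94 ± 1.57 CPM (SD, n = 4). Called genes numbered 2727, of which 1342 were higher and 1385 lower; with upper-quartile factors 1531 were higher and 1201 lower, and on log2(TPM + 1) 1101 and 1293. At least 2-fold, 204 rose and 353 fell. The genes that rose at least 2-fold went from 5.15% to 15.82% of normalised counts, and those that fell from 12.67% to 2.75%.

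At 5 volume changes of 0% oxygen, 2500 genes were called against 30% oxygen, 1273 higher and 1227 lower. At least 2-fold, 183 rose and 338 fell. PP7435_Chr3-0810.t01 stood at 704 ± 109 CPM, PP7435_Chr2-0070.t01 at 692 ± 81 CPM, PP7435_Chr1-3512.t01 at 2.49 ± 0.397 CPM and PP7435_Chr3-0238.t01 at 10.3 ± 6.42 CPM (SD, n = 4). Of 60 r features tested outside the mitochondrial chromosome, 11 were higher and 5 lower. Without replicate 4 of this group, in which such features took 0.854% of counts, these numbers were 4 and 4 of 65. The share of called genes that were higher was 50.9% in the main test, 39.6% on deposited TPM values and 60% with upper-quartile factors.

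**Figure D2:**
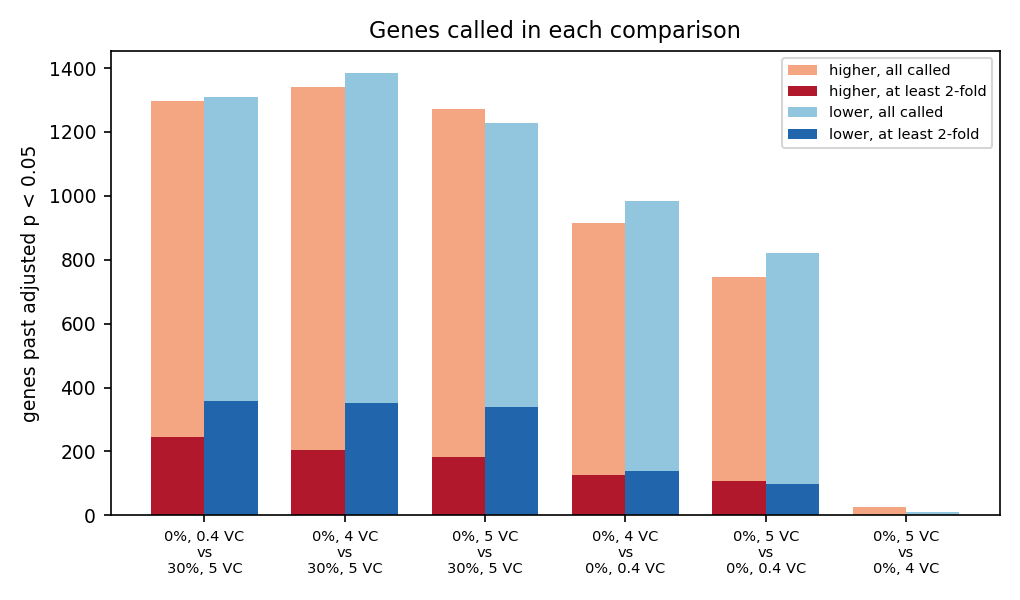
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons, with bars for genes higher and lower in the group named first and darker parts for changes of at least 2-fold. Counts run from 2727 genes for 4 volume changes of 0% oxygen against 30% oxygen down to 35 for 5 against 4 volume changes.

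The 3 comparisons with 30% oxygen share its libraries, so part of their overlap comes from the shared controls. In all, 1699 genes were called in the same direction at 0.4 and 4 volume changes and 111 in opposite directions. Independent lists would give 652 of each. Simulated unchanged groups gave 0, but no gene changes in them, so this 0 does not measure the part due to shared controls. For 0.4 and 5 volume changes the same-direction and opposite numbers were 1694 and 56, and for 4 and 5 volume changes 2165 and 1. With the controls split between the comparisons, the same-direction numbers were 1230 to 1297, 1238 to 1271 and 1521 to 1614. Fold changes correlated across genes at 0.80, 0.76 and 0.92, where simulated unchanged groups gave 0.50, 0.49 and 0.49, and at 0.69 to 0.73, 0.62 to 0.73 and 0.77 to 0.88 with the controls split. The covariances were 0.510, 0.489 and 0.576 against 0.016, 0.015 and 0.015 in the simulations. Genes are not independent replicates in these correlations. A change in one direction was called at all 3 sampling points for 1548 genes. Of the 603 genes called and changed at least 2-fold at 0.4 volume changes, 508 (84.2%) were called in the same direction at both later points.

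Oxygen supply and total time in the chemostat changed together between the 30% group and the others, so these comparisons do not separate them. Only the comparison of 5 volume changes of 0% oxygen with 30% oxygen was matched in labelled volume changes. The protocol gives 70 h after the switch and 66 h for these groups.

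How expression moved with time at 0% oxygen was tested by comparing 4 with 0.4 volume changes. PP7435_Chr4-0120.t01, on chromosome 4 (4512 nt), rose from 207 ± 73.2 to 1760 ± 171 CPM (SD, n = 4), a log2 fold change of 3.08 ± 0.19 (SE); it stood at 89.8 ± 7.32 CPM at 30% oxygen. PP7435_Chr1-1341.t01, on chromosome 1 (2112 nt), had fallen from 618 ± 16.9 CPM at 30% oxygen to 36.6 ± 4.5 CPM at 0.4 volume changes and rose again to 284 ± 28.7 CPM, a log2 fold change of 2.96 ± 0.11. PP7435_Chr3-1699.t01, on chromosome 3 (1131 nt), fell in steps, from 2240 ± 446 CPM at 30% oxygen to 292 ± 22.4 and then 21.7 ± 1.79 CPM. PP7435_Chr1-1165.t01, on chromosome 1 (2133 nt), likewise went from 7170 ± 1170 CPM to 534 ± 56.1 and 40.8 ± 4.66 CPM. Their log2 fold changes between 0.4 and 4 volume changes were -3.75 ± 0.16 and -3.71 ± 0.18, and the adjusted p of the 4 features lay between 3.03e-12 and 8.4e-10.

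**Figure D3:**
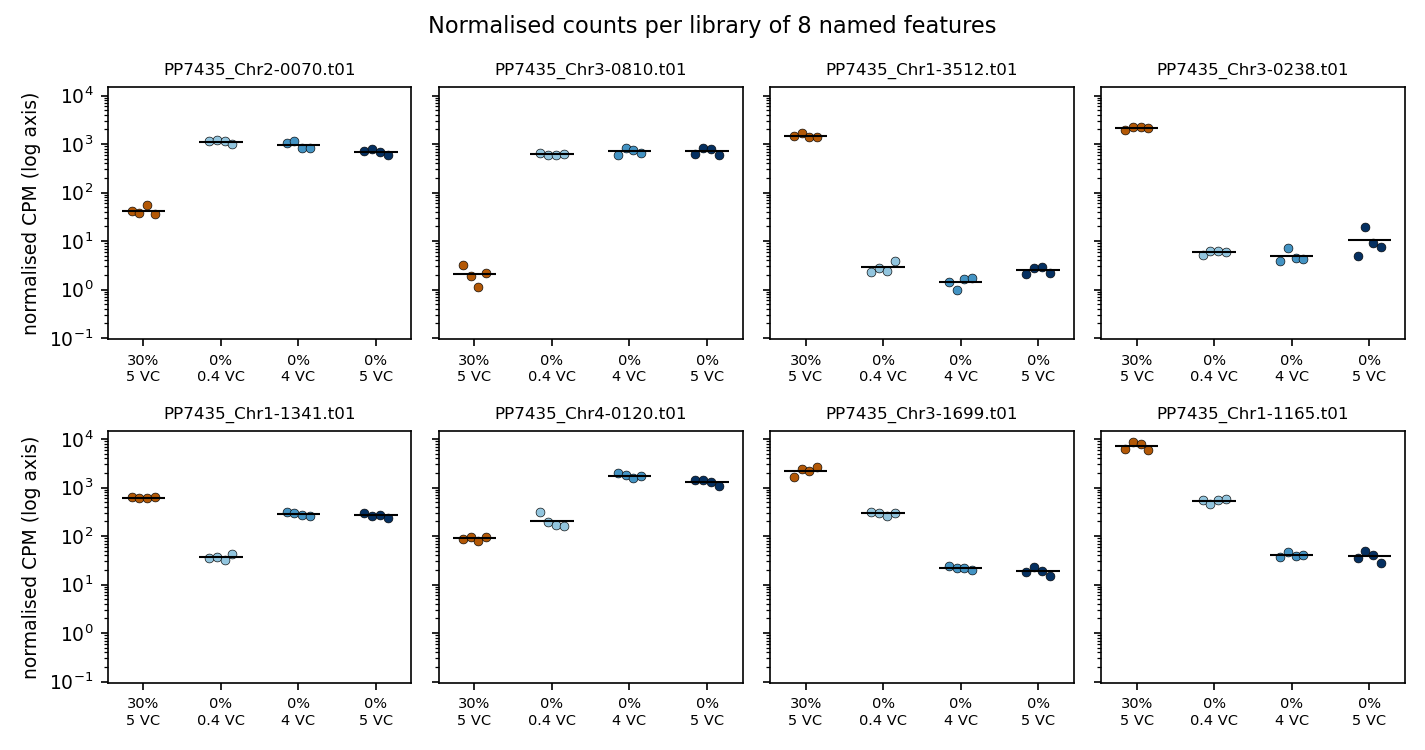
Normalised CPM on a log axis of the 8 named features in the 4 groups, 1 point per library, with a line at the mean of each group. PP7435_Chr3-0810.t01 goes from 2.1 CPM at 30% oxygen to 616 at 0.4 volume changes of 0% oxygen, and PP7435_Chr1-1165.t01 from 7170 to 534 and 40.8 CPM at 4 volume changes.

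Between 0.4 and 4 volume changes 1900 genes were called, 916 higher and 984 lower at 4 volume changes, 127 and 138 of them by at least 2-fold. Of the 2606 genes called at 0.4 volume changes against 30% oxygen, 920 (35.3%) then moved back towards the level at 30% oxygen or past it, 250 (9.6%) moved further away, and 1436 were not called between these points. Both comparisons use the libraries at 0.4 volume changes, with opposite sign, which by itself favours moves back. With those libraries split the numbers were 585 to 626 back and 147 to 174 further. Fold changes of the 2 comparisons correlated across genes at -0.35, where simulated unchanged groups gave -0.5. With the libraries split the correlation was -0.35 to -0.3. Independent lists of all libraries would give 454 of each. No such value was computed for the lists of the split fits, so 454 compares only with the 920 and 250. Among the 920, 328 were still called against 30% oxygen in the first direction at 4 volume changes, 481 were no longer called, and 111 were called in the other direction. Another 917 genes were called at 4 volume changes and not at 0.4, and 548 of them were also called between these points. The share of called genes that were higher was 48.2% in the main test, 55.8% with upper-quartile factors and 66.7% on deposited TPM values. The median log2 fold change of all genes was 0.118 on TPM values and 0.007 in the main test.

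Against 0.4 volume changes, 1567 genes were called at 5 volume changes, 745 higher and 822 lower, 109 and 97 of them by at least 2-fold. Without replicate 4 at 5 volume changes the 2-fold numbers were 99 higher and 114 lower, and the r features called higher outside the mitochondrial chromosome numbered 5 in place of 12. PP7435_Chr4-0120.t01 stood at 1320 ± 162, PP7435_Chr1-1341.t01 at 266 ± 28.2, PP7435_Chr3-1699.t01 at 19.0 ± 3.5 and PP7435_Chr1-1165.t01 at 38 ± 8.79 CPM (SD, n = 4). The share of called genes that were higher was 47.5% in the main test, 57.8% with upper-quartile factors and 59.7% on TPM values.

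Between 4 and 5 volume changes of 0% oxygen 35 genes were called, 25 higher and 10 lower at 5 volume changes, and 0 of them changed by 2-fold or more. At an unadjusted p under 0.05 there were 668 genes. None of the 8 features named above was called between these points. DESeq2 called 113 genes, and a fit of these 8 libraries alone called 0. Leaving out a single library gave 20 genes without replicate 3 and 19 without replicate 4 at 4 volume changes, and 19 without replicate 3 and 16 without replicate 4 at 5 volume changes.

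Of the 39 mitochondrial features tested, 13 rose and 1 fell at 0.4 volume changes against 30% oxygen, 14 rose and 0 fell at 4, and 13 rose and 0 fell at 5 volume changes. Adjusted over the list alone, the numbers that rose were 13, 13 and 10. Their median log2 fold changes were 0.74, 0.72 and 0.65, and all 15 members with suffix t had positive values in each of these comparisons. Of these 15, only 4, 8 and 5 were called, and 0, 8 and 5 when adjusted over the list alone. Their estimated correlation was 0.814, and with it camera gave p = 0.5, 0.45 and 0.468 for them. For all 39 features, camera with its preset correlation gave p = 0.000635, 0.00266 and 0.0015, whereas with an estimated correlation the p-values were p = 0.364, 0.423 and 0.398. Between groups at 0% oxygen, limma's camera test of these 39 gave p-values of 0.58 for 4 against 0.4, 0.747 for 5 against 0.4 and 0.645 for 5 against 4 volume changes. The last depended on single libraries: limma's camera gave 0.00409 without replicate 4 at 4 volume changes and 0.049 without replicate 4 at 5 volume changes, so it is left open.

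Mitochondrial coding features took 2.11 ± 0.517% of counts at 30% oxygen, and 2.75 ± 0.501%, 3.38 ± 1.27% and 3.41 ± 0.928% (SD, n = 4) at 0.4, 4 and 5 volume changes of 0% oxygen. Exact permutation tests against 30% oxygen gave p = 0.114, 0.143 and 0.0571. The 10 most counted features of each library together took 7.61 ± 0.343% of counts at 30% oxygen, and 11.7 ± 0.236%, 11.3 ± 1.20% and 10.7 ± 1.37% at 0% oxygen. In each of these 3 comparisons all 4 libraries at 0% oxygen lay above all 4 at 30% oxygen, which gave p = 0.0286 in exact permutation tests, the smallest that these numbers allow, and 0.172 after adjustment over the 18 tests of shares.

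**Figure D4:**
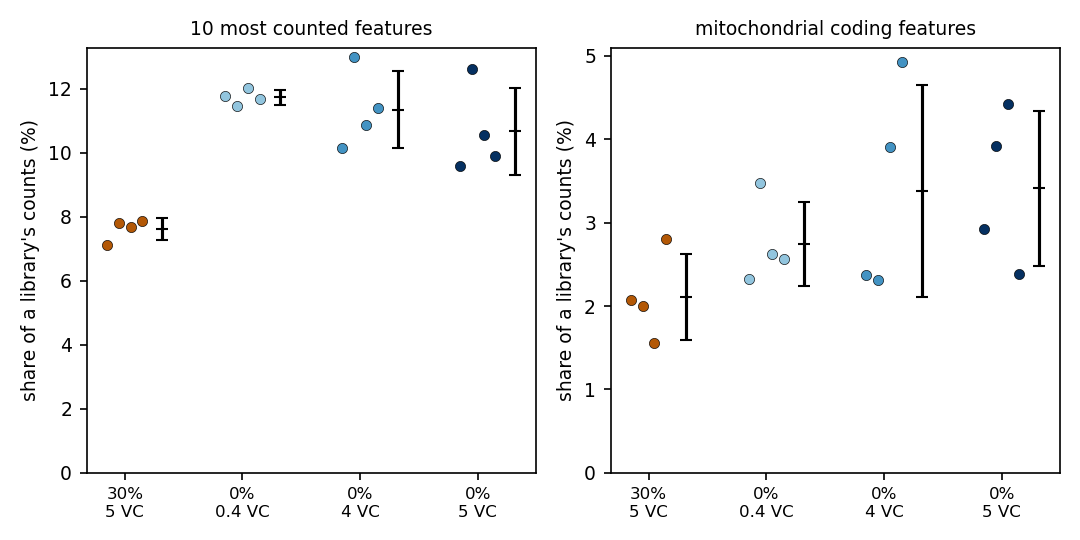
Percent of a library's counts in its 10 most counted features (left) and in mitochondrial coding features (right), 1 point per library, with bars for the mean ± SD of 4 libraries. The share of the 10 features averaged 7.61% at 30% oxygen and 11.7% at 0.4 volume changes of 0% oxygen, and the mitochondrial shares of the groups overlap.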

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

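The tests of explanations in this part, and the counts over other splits of the libraries, were chosen after the results were seen.

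In 48 sets of 4 libraries (4 library measures and 8 identifiers in 4 groups), 4 held a library far from the other 3, where chance gives about 1 in 20, or 2.4. The share of r features outside the mitochondrial chromosome was 0.854% in replicate 4 at 5 volume changes of 0% oxygen, against 0.015% to 0.038% in the others of its group. Replicate 1 at 30% oxygen held 0.028%, against 0.018% to 0.019%. PP7435_Chr3-0238.t01 reached 7.27 CPM in replicate 2 at 4 volume changes, against 3.87 to 4.41. PP7435_Chr1-1165.t01 had 451 CPM in replicate 2 at 0.4 volume changes, against 550 to 570.

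The high r share of replicate 4 at 5 volume changes was weighed further. Its total of 39887634 counts lay within the range of the other 15 libraries, which argues against depth. Only 1 of the other 3 libraries of its group lay above every library of the other groups, which argues against the sampling point. Of its excess over the other 3, 100.1% lay in r features longer than 1000 nt, the rest having been slightly lower, so ribosomal RNA left after depletion may be the source. That remains a hypothesis, since the tables do not say what the r features are.

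Several features differed between the sampling points at 0% oxygen. The first 4 identifiers below were chosen as the largest changes from 0.4 to 4 volume changes, so their difference between those points restates that choice. From 0.4 to 4 and 5 volume changes, log2 fold changes were 3.08 and 2.67 for PP7435_Chr4-0120.t01, 2.96 and 2.86 for PP7435_Chr1-1341.t01, -3.75 and -3.95 for PP7435_Chr3-1699.t01, and -3.71 and -3.81 for PP7435_Chr1-1165.t01. PP7435_Chr1-3512.t01 changed by -0.96 from 0.4 to 4 volume changes, and PP7435_Chr2-0070.t01 by -0.70 from 0.4 to 5. In all, 111 genes were called in opposite directions at 0.4 and 4 volume changes against 30% oxygen. A gene called in opposite directions against the same controls is almost bound to be called between the points as well, as all 111 were. Their median absolute log2 fold changes were 0.41 and 0.42.

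Other splits of the libraries argue against chance assignment to groups for 5 of the 6 counts of called genes, but do not exclude it. The real split gave 2606, 2727 and 2500 genes for 0.4, 4 and 5 volume changes against 30% oxygen, and the highest of the other splits 0, 150 and 0. It gave 1900 and 1567 genes for 4 and 5 against 0.4 volume changes, and the other splits at most 0. In each of these, only the real split, 1 of 35, reached its own count. The joint F test gave 3432 genes, against at most 636 in the other splits, again 1 of 100 drawn. A result of 1 of 35 is the smallest that 35 splits allow, and it was not adjusted for the number of such tests. The other splits also mix differing groups, which widens the spread within each side and lowers the number of genes called. For 5 against 4 volume changes, 3 of 35 splits gave at least the real 35 genes, so chance cannot be excluded. One of them called 803 genes, which points to a structure of these 8 libraries that their groups do not describe. It set replicates 1 and 2 at 4 volume changes and 1 and 4 at 5 volume changes against the rest. On the axis within groups described below, these libraries stood at -3.2, -17.0, -3.6 and -12.0. The rest stood at 7.6 and 12.7 (replicates 3 and 4 at 4 volume changes) and 1.7 and 13.9 (replicates 2 and 3 at 5). The split thus follows the sign of that axis, which comes from the same libraries and is not a separate test.

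The same count does not argue against chance for the mitochondrial list. A camera p at least as small as the real 0.000635, 0.00266 and 0.0015 against 30% oxygen came from 19, 20 and 18 of 35 splits, and the smallest in the other splits were 4.2e-12, 1.09e-18 and 2.46e-13. For 4 and 5 against 0.4 and 5 against 4 volume changes, with real p-values of 0.58, 0.747 and 0.645, 33, 34 and 35 splits did so, with smallest values of 7.91e-17, 5.28e-09 and 2.66e-12.

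Libraries of a group also differed along a common axis, the first component of deviations from group means over 5330 coding features of the numbered chromosomes, with 34.0% of that variance. Across 16 libraries it followed the deviation of the mitochondrial share (Pearson r = 0.92, permutation p = 0.0001; Spearman rho = 0.94, permutation p = 6e-05; both 0.0002 after adjustment over 4 tests of 2 relations), and r was 0.92 without the 2 libraries farthest along the axis. Its correlation with depth was -0.07, and 2.4% of the variance of its gene weights lay between 10 classes of coding length, which argues against depth and against length-dependent loss of RNA as the whole cause. The labels name only the replicate number as differing within a group. Between replicate numbers lay 6.0% of the variance of the axis, so little of it stays with a number across the sampling points. No other biological explanation was tested. A difference in handling or in the state of a culture at a single sampling stays open.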

How the results depend on the processing

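No named fold change and no called set test changed direction under the alternatives. The balance of higher and lower calls did turn in several comparisons, with those against 30% oxygen among them. For 4 and 5 against 0.4 volume changes it was 916 to 984 and 745 to 822, but 1076 to 853 and 931 to 679 with upper-quartile factors and 1210 to 604 and 772 to 521 on log2(TPM + 1). The counts against 30% oxygen and against 0.4 volume changes stayed within 1.5 times of the main count under every alternative run. With single libraries left out they were 2343 to 2472, 2455 to 2754 and 2178 to 2500 against 30% oxygen (0.4, 4 and 5 volume changes), and 1590 to 1958 and 1265 to 1561 for 4 and 5 against 0.4 volume changes.

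The count for 5 against 4 volume changes, 35, was 113 with DESeq2, 11 on log2(TPM + 1) and 11 on log2(TPM + 0.1), 0 in a fit of these 2 groups alone, and 16 to 41 with single libraries left out. It was 18 without both replicate 4 at 5 and replicate 2 at 4 volume changes, an alternative chosen after seeing the data. The cause was not tested.

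With fry, another of the alternatives set beforehand, all 39 mitochondrial features together kept their call in each comparison with 30% oxygen. The 15 members with suffix t alone passed the same threshold in fry only at 4 volume changes. The mitochondrial list lost its call against 30% oxygen with an estimated correlation (p = 0.364, 0.423 and 0.398 at 0.4, 4 and 5 volume changes), because its members correlate at 0.453 where camera presets 0.01. With single libraries left out its p ran from 3.7e-05 to 0.00427, 0.0003 to 0.0224 and 9.54e-05 to 0.0105 in these comparisons. For 5 against 4 volume changes it ran from 0.00409 (without replicate 4 at 4 volume changes) to 0.941, and was 0.049 without replicate 4 at 5 volume changes; the cause was not tested.

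Replicate numbers recur at every sampling point, and the protocol describes a switch of inlet oxygen between them, so libraries with the same number may share a culture. The main test, the exact permutation tests of shares and the splits of the libraries did not model this. Of 24 pairs with the same number, 9 correlated above 0.1 (range -0.45 to 0.42), and 6 of 16 libraries correlated best with their own number. The median correlation was 0 for pairs with the same number and -0.02 for pairs with different numbers. Between 4 and 5 volume changes of 0% oxygen, replicates 1 to 4 correlated at 0.41, 0.18, 0.42 and -0.2. These values do not settle whether the libraries are paired. With the replicate block the counts were 2554, 2697 and 2472 against 30% oxygen, 1843, 1532 and 29 between groups at 0% oxygen, and 3356 in the joint test. The block changed no call of the mitochondrial list, for which limma's camera gave 0.000375, 0.00205 and 0.0011 against 30% oxygen. At these depths, the smallest changes planted in simulated data were mostly missed. Only 200 genes were planted there, whereas 2606 were called in the real comparison of 0.4 volume changes with 30% oxygen. Simulated genes were also drawn independently, without the axis that real libraries of a group share. Recovery and the number of false calls in the data may therefore differ.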

Other observations

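In this part the tests of shared reads and of expression level were set out before their results were seen, and the others after.

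Genes listed next to each other tended weakly to change alike. In the order of the deposited tables, adjacent coding features of the numbered chromosomes had fold changes that correlated at 0.169, 0.194 and 0.200 across 5349 pairs of genes at 0.4, 4 and 5 volume changes against 30% oxygen. The highest of 1000 shuffles within chromosomes was 0.045, 0.049 and 0.046 (permutation p = 0.001, the smallest they can give). Genes are not independent replicates here. The correlation was 0.166 and 0.163 for 4 and 5 against 0.4 volume changes, and still 0.118 for 5 against 4, where few genes were called. Deviations of single libraries from their group means gave -0.068 to 0.129, with a median of 0.047, so part of the likeness is present without a difference in condition. For 0.4 volume changes the correlation fell to 0.061 for the second neighbour and 0.005 for the tenth. Among genes changed at least 2-fold there, 102 adjacent pairs moved in the same direction and 28 in opposite directions, where shuffles gave 33.3 and 30.3 on average. The table order resembles the chromosomal order of another assembly, ASM2700v1: 2283 of its 5031 distinct runs of 3 gene lengths were found, against at most 1 with lengths shuffled.

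The first and last 20 coding features of each numbered chromosome, in the order of the deposited tables, changed more often. Whether they lie at the ends of the chromosomes was not checked, since coordinates were not used. At least 2-fold changes against 30% oxygen were called in 18.1%, 21.2% and 21.9% of these 160 features at 0.4, 4 and 5 volume changes, and in 10.7%, 9.8% and 8.9% of the others. Rotating the calls along each chromosome gave an adjusted permutation p of 0.0162, 0.0025 and 0.0025 over 15 tests. With 40 features per end the first of these was not past the threshold (adjusted permutation p = 0.0849). From 0.4 to 4 volume changes 17 of the 160 features rose and 4 fell at least 2-fold.

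For the likeness of adjacent genes, 3 explanations were tested at 0.4 volume changes. Without the 82 features that held a non-whole count in any library the correlation was 0.166, which argues against reads shared between similar neighbours. Shuffles within 10 classes of mean expression reached at most 0.039 and within 10 classes of coding length 0.046, which argues against similar level or length. Shared regulation of neighbours and transcripts that run into the next gene both stay open, since strand and coordinates were not used here.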
